A study of Homo sapiens with 9 samples.

How the data were processed

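Small RNA of HUVEC was sequenced in 9 libraries: 3 of input RNA, 3 after immunoprecipitation with an anti-VEGF-A antibody and VEGF-A165, and 3 with the antibody alone, per the labels. Libraries followed MSR-seq and the processing notes of the submitters name the genome build hg38. The aligner, the counting tool and the annotation are not given in the sources used here. Groups were taken from the sample titles.

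The files hold the authors' own comparisons. For each of 1071 entries the authors deposited, per the file headers, a mean normalised count, a log2 fold over input with its standard error (log2 units), a Wald statistic (a score) and a p-value with its adjusted p-value, once for the VEGF immunoprecipitation and once for the control immunoprecipitation. The file's notes describe the control as an IgG control, whereas the labels and the design text describe an antibody against VEGF-A without VEGF-A165; the libraries are called the control as labelled. The columns have the layout of DESeq2, and the authors' filter column carries its name, per the file headers. The second table gives, per the file headers, the authors' average log2 fold over input, an average −log10 of an adjusted p-value and a combined z (a score) for 235 families. The per-library values were not used here, so the planned tests on read counts, the class sums, the paired fit and the leave-one-out fits were not run, and the tests below, chosen after seeing what the tables hold, replace them.

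The construction of the deposited columns was checked on the values. The authors' log2 difference equalled the fold over input of the VEGF immunoprecipitation minus that of the control plus a constant of 0.70 in every row, whose origin is not stated. Its standard error was the root of the sum of both squared standard errors. The deposited p-value of that difference equalled the one-sided normal p of the z multiplied by a factor of 3.43 in each of 751 rows where it could be computed. That factor makes the p smaller than the z alone gives: 82 entries called significant have a z below the one-sided 5% normal quantile. The deposited input filter equalled a log2 fold above 0.5 in every row, without the adjusted p that the notes state.

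The 2 base mean columns had the same total, and group means were derived from them as 3 against 3 libraries. Both comparisons gave near-equal input means (median absolute log2 difference 0.0151). Shares and CPM come from these group means, which cover no spread. The difference D between the immunoprecipitations was computed without the constant, so it lies close to the log2 ratio of library shares, called the share scale, from which it departs where the 2 input estimates differ. It was tested with a two-sided normal test on D over the deposited standard error, with Benjamini-Hochberg adjustment over 1071 entries at 0.05. That standard error counts the shared input error in both folds, which makes it larger than needed. The normal test on simulated differences with the deposited standard errors and 200 changed of 1071 entries recovered 34% at a log2 change of 0.5, 62% at 1, 78% at 2 and 94% at 4, with 4.29% false among its calls. It takes the errors at face value, with only 3 libraries per group.

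RNA lists were fixed before the data were examined, matched by name and, for unnamed loci, by the GENCODE v29 small RNA at the same place (at least 50% reciprocal overlap, 186 of 245 loci). Lists with at least 3 members were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the ranks of D with a preset correlation of 0.01, and 5 of 5 shifted lists and 0 of 15 unshifted lists were called in a test on simulated data over 1071 entries. The named genes were also fixed beforehand: the 10 largest rises and falls with an adjusted p below 0.05 and a mean of at least 10 CPM over the immunoprecipitations, 5 each over input, and a list of canonical RNAs. The rule's requirement that the groups' values do not overlap could not be applied. Families were ranked by the authors' combined z because no mean count is given. Positions and lengths come from RefSeq on GRCh38.p14, where 788 of 1071 symbols matched, and hosts from GENCODE v29 on GRCh38. A tRNA entry took the median length of its RefSeq copies, which gave 1058 entries a length. Copies of multigene families, 21 symbols listed more than once (44 rows) and 18 entries overlapping another are uncertain, since reads may be shared, and whether counting used strand is not given in the sources used here.

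Alternatives were other centrings, a t distribution with 4 degrees of freedom, the shared input error taken out, a base mean of at least 10, a threshold of 0.01, a log2 difference of at least 1, collapsed copies, and for lists a correlation of 0.05 and the z as the statistic. A ratio of class shares was called unmoved when it changed by less than 0.1 on the log2 scale, a bound set here because no spread or depth is known. GC content was taken from GENCODE v29 transcript sequences. Permutation tests used 100000 resamples. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.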

Results

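Small RNA was isolated from HUVEC, primary endothelial cells of the human umbilical vein, which were grown in a medium supplemented with a growth kit that contains VEGF. The fraction was generally below 200 nucleotides. This RNA was sequenced directly as input. Per the labels and the design text, it was also incubated with an antibody against VEGF-A, either with added VEGF-A165 (the VEGF immunoprecipitation) or with the antibody alone (the control immunoprecipitation). VEGF-A165 is an isoform of vascular endothelial growth factor A that binds heparan sulfate. Each of the 3 groups held 3 libraries, 9 in all, made with MSR-seq, a multiplex small RNA method. The values analysed here were the authors' own comparisons of each immunoprecipitation with input for 1071 small RNA entries, and no values per library were used, so the depth of each library is unknown and no spread between replicates can be given. The ± values below are standard errors, taken from the authors' deposited table for folds over input and combined from it for differences between the immunoprecipitations. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the errors may cover technical spread alone.

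The first question was which kinds of RNA made up each group. Transfer RNA made up most of input and of the control immunoprecipitation and a smaller share of the VEGF immunoprecipitation, where larger shares went to spliceosomal, ribosomal, nucleolar and 7SL RNA. Group means implied by the authors' deposited table gave tRNA 80.9% of the normalised total in input, 81.7% in the control immunoprecipitation and 50.7% in the VEGF immunoprecipitation. Small nuclear RNA made up 7.79%, 6.56% and 21.0% in the same order. Small nucleolar RNA made up 2.25%, 1.74% and 7.66%. The rRNA entries, which are 5S and 5.8S rRNA and related loci, made up 8.10%, 9.19% and 16.3%. Within them 5.8S rRNA, a part of the large ribosomal subunit, made up 1.07%, 0.953% and 3.88%. 7SL, the RNA of the signal recognition particle, made up 0.208%, 0.307% and 3.50%, which was an 11.4-fold higher share with VEGF-A165 than without it. These shares carry no error, since they come from group means, and a class's share also moves when another class takes more of the library.

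**Figure D1:**
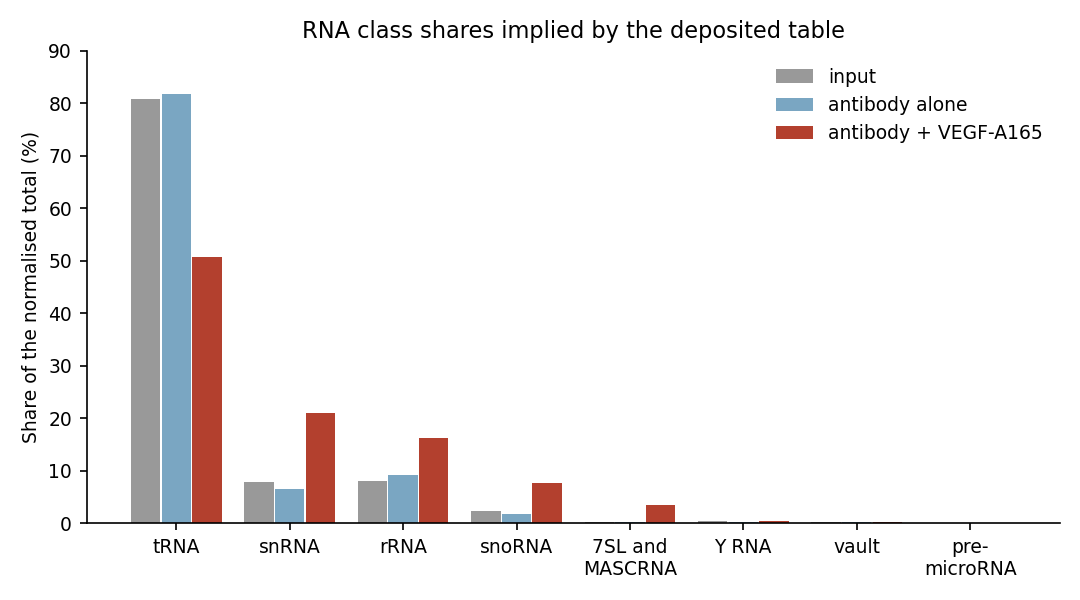
Shares of the normalised total (%, y axis) taken by 8 RNA classes in input, the control immunoprecipitation (antibody alone by its label) and the VEGF immunoprecipitation, as implied by the group means in the authors' deposited table. Bars carry no error because no values per library were used. The tRNA bar stands at 50.7% with VEGF-A165 against 81.7% without it, and the snRNA bar at 21.0% against 6.56%.

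The main question was which RNAs took a larger share of the VEGF immunoprecipitation than of the control. Both are scaled to the same total, so a rise or fall is a change in share. The amount of RNA recovered in each is unknown. Several canonical non-coding RNAs of ribonucleoproteins rose. 7SK, which holds the elongation factor P-TEFb inactive, was 15.6-fold higher (log2 difference 3.97 ± 0.72, adjusted p = 9.44e-08), and RPPH1, the RNA of RNase P, was 16.0-fold higher (4.00 ± 0.45, adjusted p = 4.57e-18). RMRP, the RNA of RNase MRP, was 10.2-fold higher (3.35 ± 0.43), and RN7SL1 and RN7SL2 were 11.9-fold and 11.8-fold higher (3.57 ± 0.82 and 3.56 ± 0.79). These last 2 genes are near-identical, so the split of reads between them is uncertain. In GRCh38.p14, 7SK lies on chromosome 6 from 52995620 to 52995951, RPPH1 on chromosome 14 from 20343071 to 20343411, and RMRP on chromosome 9 from 35657750 to 35658019.

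Of 1071 entries, 461 rose and 326 fell in the VEGF immunoprecipitation relative to the control at a Benjamini-Hochberg adjusted p below 0.05, and 284 did not pass. The test took the difference of the deposited folds over input, in which the input cancels apart from the small difference between its 2 estimates, and its combined standard error as a two-sided normal statistic. The split depended on the scaling: with a constant of 0.70 that the authors added to every log2 difference it was 614 higher and 188 lower, and after centring on the median of all entries, which lay at 0.54, it was 368 higher and 410 lower. Changes below are on the share scale unless a scaling is named.

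Spliceosomal RNAs remove introns from pre-mRNA. Of the 15 U1 entries 13 rose and 2 did not pass, and all 4 U2, all 4 U4 and all 5 U5 entries rose, with the same counts when adjusted over the list alone. RNU1-1 is listed 2 times and its copies rose by 2.07 ± 0.36 and 2.03 ± 0.36 on the log2 scale. RNU2-1 rose by 1.67 ± 0.19, RNU4-1 by 2.05 ± 0.35 and RNU5A-1 by 1.28 ± 0.13. All 4 RNAs of the minor spliceosome, which removes a rare class of introns, also rose: RNU12 by 3.15 ± 0.39, RNU4ATAC by 3.00 ± 0.27, RNU6ATAC by 2.63 ± 0.51 and RNU11 by 1.62 ± 0.25. Of the 7 U6 entries 1 rose and 6 did not pass. RNU6-1 stood at 0.09 ± 0.11, at 0.78 with the authors' constant and at -0.46 after centring on the median, so its direction depended on the scaling. RNU7-1, the RNA that processes histone mRNA ends, did not pass (-0.50 ± 0.31, and 0.20 with the authors' constant), and after centring on the median it passed as lower (-1.04). Of the 6 U7 entries 1 rose and 5 did not pass, and their median of 0.27 turned to -0.27 after centring on the median.

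Small nucleolar and Cajal body RNAs, which guide chemical modification of rRNA and snRNA, parted by type. Of the 140 box H/ACA snoRNAs 99 rose, 3 fell and 38 did not pass, with a median log2 difference of 1.94. Of the 39 scaRNAs 26 rose, none fell and 13 did not pass, with a median of 2.24. The 221 box C/D snoRNAs went both ways: 72 rose, 63 fell and 86 did not pass, or 69, 63 and the rest when adjusted over the list alone, and their median of 0.11 turned to -0.43 after centring on the median. For the H/ACA and scaRNA lists, adjusting over the list alone gave the same counts.

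Among all entries with an adjusted p below 0.05 and a derived mean of at least 10 CPM over the 2 immunoprecipitations, the 10 largest rises belonged to snoRNA-type entries, microRNA-annotated loci and RPPH1. The highest was LOC124904669 on chromosome 1 from 116278606 to 116278821, at a place that GENCODE assigns to Rfam family RF00012, the U3 snoRNA, with 28.5-fold more in the VEGF immunoprecipitation (4.84 ± 0.46, adjusted p = 1.29e-24). LOC124904363, in an intron of AC006305.1 on chromosome 18 from 56079394 to 56079594, rose by 4.43 ± 0.64. SNORD133, in an intron of LARP4 on chromosome 12, rose by 4.31 ± 0.72, RNU105C by 4.20 ± 0.50, SNORD3I by 4.18 ± 0.41 and SNORD141B by 4.16 ± 0.62. MIR663B rose by 4.44 ± 0.60, MIR663A by 4.14 ± 0.59 and MIR4485 by 4.00 ± 0.63. MIR4485 lies within MTRNR2L8, a nuclear copy of mitochondrial rRNA sequence, so its reads could not be told apart from rRNA fragments by position, and SNORD3I and LOC124904669 belong to the multicopy U3 family, where reads may be split between copies. SNORD141B, MIR663A and RPPH1 overlap exons of EEF1A1P13, MIR663AHG and AL355075.4, so reads of those genes could not be told apart by position either.

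The RNAs that fell were mainly tRNAs, short box C/D snoRNAs and microRNA loci. Of the 276 cytosolic tRNA entries 214 fell, 19 rose and 43 did not pass, and the list adjusted alone gave 214 and 20. Their median log2 difference was -0.78, which the authors' constant moved to -0.08. tRNA-Phe had the lowest median of the isotypes, with all 10 entries lower and a median of -2.63, or -1.94 with the constant; TRF-GAA3 (its second copy) fell by 3.16 ± 0.11 on the log2 scale and TRF-GAA6 by 3.59 ± 0.36. tRNA-Ala fell in 27 of 29 entries with a median of -1.61. tRNA-Lys was at the other end with 7 entries higher, none lower and 12 that did not pass, and its median of 0.15 turned to -0.40 after centring on the median. Of the 22 mitochondrial tRNAs 13 fell and 5 rose, or 14 and 5 when adjusted over the list alone, and their median of -0.57 turned to 0.13 with the authors' constant. Many of these tRNA genes are near-identical copies, so their entries are not independent.

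Among the snoRNAs, SNORD38D fell by 5.63 ± 0.44 on the log2 scale (49.6-fold, adjusted p = 5.58e-37), SNORD2 by 5.48 ± 0.45 (44.7-fold), while SNORD38B stood at -4.71 ± 0.33 and SNORD92 at -4.58 ± 0.48. LOC124902338, in an intron of MAN1B1, stood at -4.61 ± 0.50, SNORD62A at -3.88 ± 0.51 and SNORD25 at -3.74 ± 0.44, each lower in the test. Most of these differences came with gains over input in the control. In the authors' deposited table, the control and VEGF folds over input were 5.31 and 1.42 for SNORD62A and 5.05 and 0.45 for LOC124902338. They were 4.24 and -1.39 for SNORD38D, 3.65 and -1.83 for SNORD2, 2.50 and -2.21 for SNORD38B and 2.85 and -0.89 for SNORD25. SNORD92 did not pass in the control (0.22) and was below input with VEGF-A165 (-4.35). MASCRNA, the tRNA-like RNA cut from the end of MALAT1, fell by 4.08 ± 0.32 and was below input in both immunoprecipitations (-1.42 in the control, -5.50 with VEGF-A165). SNORD2 lies within EIF4A2 on chromosome 3 from 186784796 to 186784865. SNORD38D, SNORD2, SNORD38B, SNORD92, LOC124902338, SNORD62A, SNORD25 and MASCRNA stayed below 0 with the authors' constant and after centring on the median.

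The 73 microRNA-annotated entries are precursor loci, and their median log2 difference was -0.75, or -0.05 with the authors' constant. In them 24 fell, 20 rose and 29 did not pass, or 23 and 20 with adjustment over the list alone. Of the 9 measured members of the endothelial microRNA list 4 fell, namely MIR21 (-6.61 ± 0.69, adjusted p = 1.02e-20), MIR126 (-3.20 ± 0.61), MIR221 and MIR222, none rose, and the same 4 fell when adjusted over the list alone. MIR21 and MIR126 had low means in the VEGF immunoprecipitation, 0.168 and 0.287 CPM against 15.8 and 2.65 CPM in the control. Of the markers of other cell types, MIR155 of the leukocyte list did not pass (-0.63, and 0.07 with the authors' constant), and the erythroid, smooth muscle and fibroblast, and epithelial lists had no member in the table. Y RNAs and vault RNAs, short RNA polymerase III transcripts of cytosolic particles, mostly rose on the share scale. RNY3, RNY1 and RNY5 rose by 1.38 ± 0.15, 1.25 ± 0.28 and 0.92 ± 0.13, while RNY4 fell by 1.01 ± 0.13. VTRNA1-1 rose by 1.01 ± 0.16, VTRNA1-2 by 0.61 ± 0.17 and VTRNA1-3 by 0.60 ± 0.16, while centring on the median moved VTRNA1-2 to 0.06 and VTRNA1-3 to 0.05 and ended both calls. VTRNA2-1 did not pass (-0.30 ± 0.29, or 0.39 with the constant), and after centring on the median it passed as lower (-0.85). The 5.8S rRNA entries RNA5-8SN2 and RNA5-8SN4 rose by 2.05 ± 0.19 and 2.04 ± 0.20. The 5S entry RNA5S1, listed 2 times, rose by 0.45 ± 0.19 and 0.44 ± 0.19, which turned to -0.10 after centring on the median, and neither copy passed with a t distribution with 4 degrees of freedom. The 18S, 28S and mitochondrial rRNAs and protein-coding mRNA of the fixed lists were not analysed here.

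**Figure D2:**
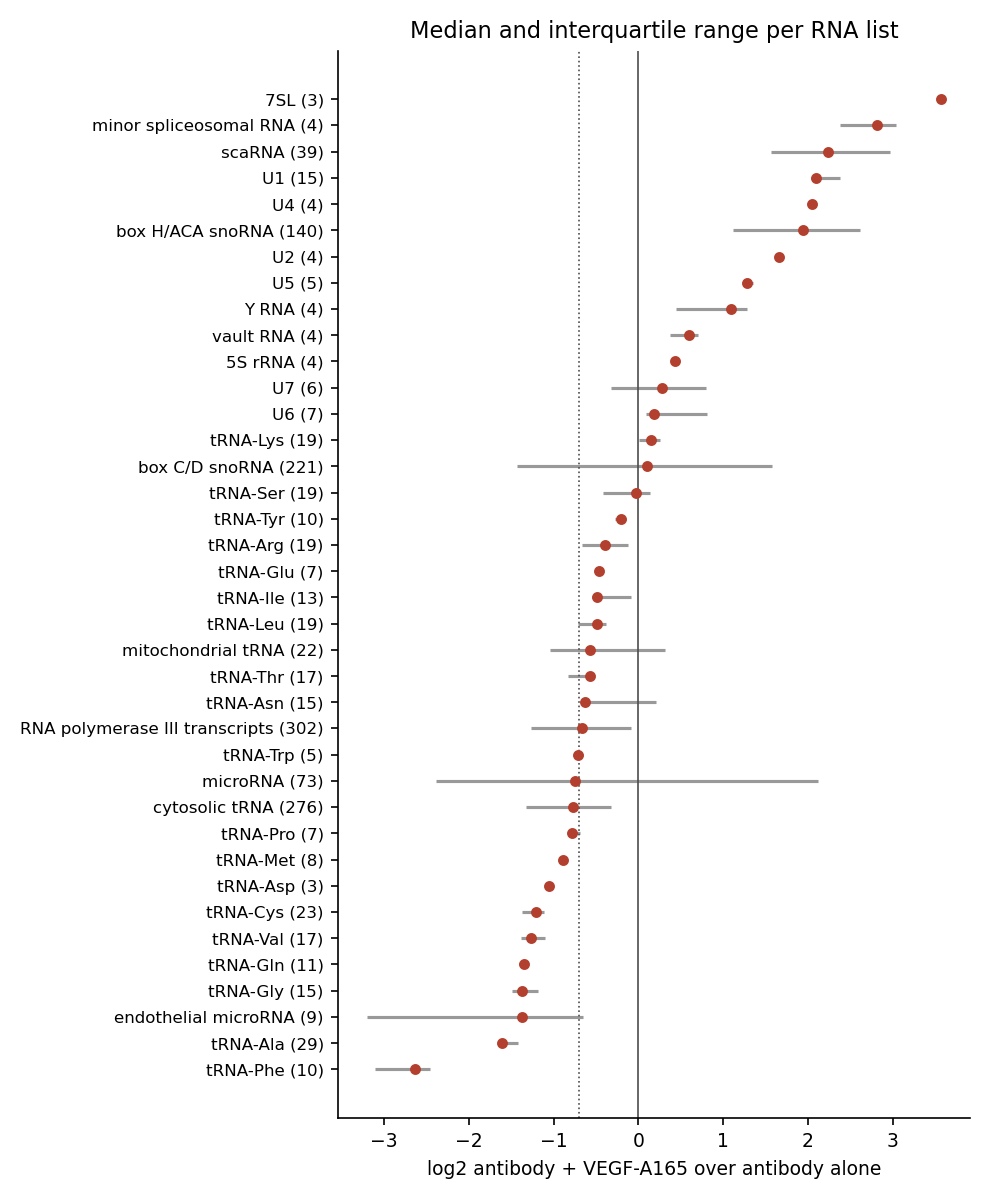
Median (points) and interquartile range (lines) of the log2 difference between the VEGF and the control immunoprecipitation (x axis) for each RNA list with at least 3 entries (y axis, number of entries in brackets). The solid line marks 0 on the share scale and the dotted line marks where 0 falls with the authors' constant, and lists between the lines change sign with it. The 7SL median stands at 3.57 and the tRNA-Phe median at -2.63.

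A competitive test of the ranks of the differences (limma's cameraPR with a preset correlation of 0.01) compared each list with the other entries. Of 38 lists tested, 20 had an adjusted p below 0.05. The higher ones were box H/ACA snoRNA (adjusted p = 1.67e-07), scaRNA (adjusted p = 1.86e-05), U1 (adjusted p = 0.00535) and 7SL (adjusted p = 0.0203). The U1 call was lost with collapsed copies (adjusted p = 0.456) and the 7SL call with z as the statistic (adjusted p = 0.134). U2 (adjusted p = 0.363), U4 (adjusted p = 0.158), U5 (adjusted p = 0.496) and minor spliceosomal RNA (adjusted p = 0.0502) did not pass this test, although each of their entries rose, and with z as the statistic they passed as higher (adjusted p = 0.00377, 0.0154, 0.00294 and 0.0105 in the same order). Those lower included cytosolic tRNA (adjusted p = 1.43e-17), tRNA-Ala, tRNA-Phe, RNA polymerase III transcripts (adjusted p = 7.03e-15, with a median of -0.66 that turned to 0.03 with the authors' constant) and the endothelial microRNAs (adjusted p = 0.00318). The polymerase III list of 302 entries holds the 276 cytosolic tRNAs, so its call largely repeats theirs. It had 37 entries higher and 215 lower, against 19 and 214 for the cytosolic tRNAs alone. Its other members mostly rose, among them 7SK, RPPH1, RMRP and 7SL, while RNY4 fell. With collapsed copies tRNA-Ala did not pass (adjusted p = 0.0619), and tRNA-Phe had too few members left to be tested. The box C/D list was called lower (adjusted p = 0.0203) although its median of 0.11 lies above 0, because it ranks below the other entries. The medians of the Y RNA and vault lists lie above 0 and the test's direction was down without passing (adjusted p = 0.954 and 0.944). With a correlation of 0.05 the box C/D list did not pass (adjusted p = 0.216), nor did the microRNA list (adjusted p = 0.159) or mitochondrial tRNA (adjusted p = 0.109). A correlation could not be estimated without values per library.

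The authors made their own calls, and their deposited table marks 739 entries as significant against the control and 419 of those as TP, the class that also exceeds its input filter. The TP entries comprise 290 snoRNAs, 57 snRNAs, 29 scaRNAs, 18 microRNA loci, 11 tRNAs, 8 rRNA entries, 3 7SL genes and 1 entry each of RMRP, RPPH1 and TERC, the telomerase RNA, in the authors' deposited table. Of the TP entries 350 also rose in the two-sided test on the share scale, and 8, all of them tRNAs, fell. Of the 739 entries in the authors' deposited table, 61 fell on the share scale, and those 61 were all tRNAs. In 42 entries the authors' input filter was passed with an adjusted p over input of 0.05 or more, although the file's notes state a threshold of 0.05, and 38 of those are TP. With the stated filter 381 entries would be TP.

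The second question was which RNAs the VEGF immunoprecipitation enriched over the small RNA it was taken from. Of 1071 entries 409 were higher than input and 429 lower in the authors' deposited table at an adjusted p below 0.05. The largest rises with a derived mean of at least 10 CPM were SNORD133 (6.54 ± 0.44), SNORD141B (4.97 ± 0.41), RN7SK (4.68 ± 0.49), MIR663B (4.67 ± 0.44) and MIR663A (4.49 ± 0.44) in the authors' deposited table, in log2 units. Derived input means were low for SNORD133 (0.320 CPM), SNORD141B (0.622), MIR663B (1.49) and MIR663A (2.66), against 45.6 CPM for RN7SK. Those with low input met the minimum through the immunoprecipitation, and their folds rest on few input reads. Under the same minimum the lowest were MASCRNA (-5.50 ± 0.31), SNORD114-28 (-5.32 ± 0.43), SNORD90 (-5.05 ± 0.46), SNORD114-20 (-4.96 ± 0.48) and SNORD114-25 (-4.75 ± 0.42) in the authors' deposited table. The SNORD114 RNAs come from introns of MEG8 in an imprinted cluster on chromosome 14, where SNORD114-28 lies from 100989130 to 100989200. Of the canonical RNAs, RNY5 was above input in the authors' deposited table (0.41 ± 0.13, adjusted p = 0.00187) and RNY4 below it (-1.71 ± 0.09, adjusted p = 3.25e-80), while VTRNA1-1 (0.12 ± 0.15, adjusted p = 0.43) did not pass.

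By its labels the control immunoprecipitation measures what the antibody recovers without added VEGF-A165, although the deposited notes describe an IgG control. It stayed closer to input in its tRNA share, and it was below input for more entries: 161 were higher and 597 lower in the authors' deposited table. Centring on the median of the table gave 368 higher and 307 lower, so the balance there rests on the scaling. With a derived mean of at least 10 CPM, the largest rises were SNORD62A (5.31 ± 0.26), LOC124902338 (5.05 ± 0.28), SNORD38D (4.24 ± 0.16), SNORD2 (3.65 ± 0.12) and TRF-GAA6 (3.14 ± 0.15) in the authors' deposited table. Under the same minimum those lowest were LOC124904669 (-2.88 ± 0.26), TRY-ATA1 (-2.81 ± 0.19), LOC124904741 (-2.52 ± 0.11), LOC124905170 (-2.52 ± 0.11) and SNORD3I (-2.29 ± 0.17) in the authors' deposited table. Of the canonical RNAs that rose with VEGF-A165, some were below input here, such as RNU2-1 (-0.29 ± 0.06), RNU5A-1 (-0.42 ± 0.04), RNA5-8SN2 (-0.18 ± 0.05) and RNU12 (-0.67 ± 0.16), and RNU6ATAC was above it (1.18 ± 0.20), in the authors' deposited table. RN7SK (0.71 ± 0.53), RN7SL1 (0.51 ± 0.40), RPPH1 (0.03 ± 0.27) and RNU1-1 (-0.07 ± 0.08 and -0.05 ± 0.08) did not pass in the authors' deposited table.

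Entries beyond 0.5 log2 units of input in the same direction in both immunoprecipitations were counted to describe what they share. There were 47 higher in both and 200 lower in both in the authors' deposited table. Independent lists of the same sizes would share 35.0 and 170, and simulated unchanged RNA with shared input gave 0 in each direction. The simulation covers RNA that did not change, so its 0 gives no expected overlap for the entries that did change over input. The input libraries are common to both comparisons and could not be divided without values per library, so for RNAs that changed part of the excess may come from the shared input.

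**Figure D3:**
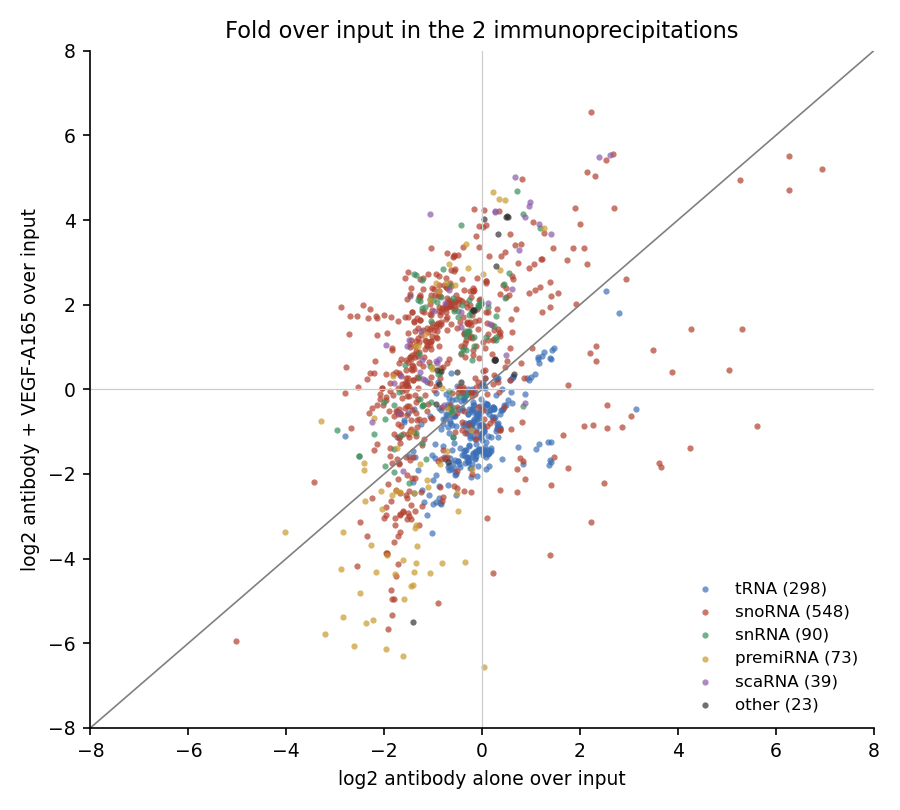
Each point is 1 of 1071 entries, with the log2 fold of the control immunoprecipitation over input on the x axis and that of the VEGF immunoprecipitation over input on the y axis, both from the authors' deposited table, coloured by RNA class with the number of entries. Points above the diagonal were higher with VEGF-A165 on the share scale, and most tRNA points lie below it and most snRNA and scaRNA points above it.

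The authors' second deposited table summarises entries they called by 235 families, with no mean count, so the 10 with the largest combined z are named. It leaves out SNAR-G2, a small NF90-associated RNA called TP, so it does not cover every TP entry. The 10 families were U3 (combined z 40.5, average log2 fold over input 1.52), U1 (35.0 and 2.05), U2 (28.2 and 1.36), U13 (26.3 and 2.03), 5.8S rRNA (24.4 and 1.87), U8 (17.5 and 1.05), the C/D box 3 pseudogene 3 (17.4 and 1.60), SNORA70 (16.7 and 1.91), mitochondrial tRNA-Leu (16.4 and 1.97) and U4 (16.3 and 1.83) in the authors' deposited table. The mitochondrial tRNA-Leu average equals the fold of TRNL1 alone. TRNL2, the other mitochondrial tRNA-Leu, was below input with VEGF-A165 (-3.39 ± 0.13) and was not called, in the authors' deposited table. How members were weighted is not given in the sources used here.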

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

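The tests on tRNA-Phe in this part were chosen after the pattern was seen. There were 178 entries above input in the VEGF immunoprecipitation and below it in the control in the authors' deposited table, and 69 were the other way round, each with an adjusted p below 0.05 over input in both and a difference that also passed its own test. The first group held 133 snoRNAs and 29 snRNAs, and the second held 57 tRNAs and 12 snoRNAs. Which side of input an entry falls on depends on the scaling. In the control, 161 higher and 597 lower became 368 and 307 when centred on the median. The counts of 178 and 69 and their classes were not recomputed under another scaling. The labels of the 2 immunoprecipitations differ in added VEGF-A165, and each library's own processing cannot be separated from it here.

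tRNA-Phe stood out among the 69: all 10 of its entries were above input in the control, and 9 were below it in the VEGF immunoprecipitation, in the authors' deposited table. Its median difference lay -1.92 from that of the other cytosolic tRNAs and -2.06 from that of 107 others of its own lengths. These values exclude neither the fall of the tRNA class as a whole nor length, because tRNA-Phe was picked as the lowest of 21 isotypes and its 10 entries are near-identical copies that weigh as little more than 1 RNA. Mitochondrial TRNF, which carries the same amino acid, was also above input in the control and below it with VEGF-A165. It differed by -2.61 ± 0.30 between the immunoprecipitations and lay -2.05 from the median of the other mitochondrial tRNAs, a comparison that was also run. TRNF is the mitochondrial tRNA-Phe, a separate gene outside the 10 cytosolic entries. As 1 entry looked at after the pattern was seen, it decides nothing here. A difference in recovery with VEGF-A165, an effect of the control libraries and shared reads also stay open.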

How the results depend on the processing

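Every alternative here was chosen after seeing the data, since the alternatives fixed beforehand (other normalisations, other count tests, count filters, fewer groups in the fit, a voom fit, pseudocounts, leaving out each replicate, class and family fits, and an estimated correlation or fry for lists) need values per library and were not run. No paired analysis was possible because the table holds comparisons and no values per library. For the same reason other splits of the samples were not run. The number that rose stayed within 1.5 times of 461 under all alternatives (368 to 614). The number that fell went from 326 to 188 with the authors' constant, to 214 at a log2 difference of at least 1 and to 159 with 1 entry per symbol or anticodon, where 840 entries remain, which shows how many copies the count holds. The authors' 739 significant entries became 470 without both the constant and the factor and 368 when centred on the median without the factor; their 419 TP entries ranged from 314 to 401. Above input in the control, 161 became 96 at a log2 fold above 0.5 and 368 when centred on the median, where 597 below it became 307. The log2 ratio of tRNA shares, VEGF over control, of -0.69 became -0.57 without rRNA entries, and VEGF over input of -0.67 became -0.54. The 20 lists called became 13 at a correlation of 0.05 and 9 with collapsed copies, where 26 lists kept enough members to be tested and 4 of the lists called did not. With z as the statistic the lists Y RNA (adjusted p = 0.233), vault RNA (0.343), U6 (0.652), 5S rRNA (0.604) and tRNA-Lys (0.764) turned from lower to higher without passing in either. Centred on the median, RNU6-1 turned to -0.46 and the RNA5S1 copies to -0.10 and -0.0956. Of 224 other settings of named genes 210 kept their side of the threshold with no call reversed; among these RNU7-1 and VTRNA2-1, which did not pass, turned to 0.20 and 0.39 with the authors' constant. Centred on the median both passed as lower (-1.04 and -0.85). The cause of these changes was not tested beyond the construction of each alternative. Depth per library is unknown, and 150 entries have a base mean below 10.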

Other observations

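The families, members and tests in this part were chosen after their values were seen, except the tests of GC content and abundance for SNORD113 and SNORD114. sNAR RNAs, small RNAs that bind NF90, rose in 11 of 12 entries, with a median log2 difference of 3.13, and 8 of these were still higher after centring on the median. SNAR-B1 rose by 3.10 ± 0.50, SNAR-E by 3.44 ± 0.51 and SNAR-A1 by 0.82 ± 0.37. The 12 U3 entries with SNORD3 names, the pseudogene SNORD3P3 included, all rose, by 1.49 to 4.18, and so did 26 of 29 unnamed loci at Rfam family RF00012. SNORD116, an imprinted snoRNA cluster, had 2 groups of copies: SNORD116-25, SNORD116-26, SNORD116-27, SNORD116-29 and SNORD116-30 rose by 3.45 to 3.74, and none of the other 18 copies passed (median 0.23, which falls below 0 after centring on the median). Base means of the VEGF comparison were 36.8 to 114 in the copies that rose and 3.42 to 27.9 in the other 18. A missing call at such a low base mean says little. Copies with near-equal values may share reads and are not independent. Mitochondrial tRNAs also parted, from TRNL1 (2.59 ± 0.20), TRNN (1.30 ± 0.15) and TRNQ (1.06 ± 0.15), which rose, to TRNL2 (-2.36 ± 0.16) and TRNF (-2.61 ± 0.30), which fell. TRNH was above input in both immunoprecipitations in the authors' deposited table, at 1.79 with VEGF-A165 and 2.81 without it. Of 11 tRNAs the authors called TP, 8 fell on the share scale, among them TRL-CAG1 (-0.51 ± 0.10) and TRR-ACG2 (-0.64 ± 0.08), and these turned to 0.19 and 0.06 with the authors' constant.

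Longer RNAs had larger differences. Across 1058 entries, which are not independent replicates, RefSeq length and D had a rank correlation of 0.659 (permutation p = 1e-05, the smallest possible), and the median lay at -0.65 at 70 nt or less (n = 82), against the trend, then rose from -0.96 at 71 to 80 nt (n = 320) to 1.09 at 91 to 110 nt (n = 147) and 2.09 at 131 to 150 nt (n = 188). The median was 2.03 at 151 to 200 nt (n = 48). It was largest, at 2.73, above 200 nt (n = 69), which is longer than the fraction generally held. RNA class standing in for length was argued against only for the broad classes, by a rank correlation of 0.457 within them. The snoRNA class pools types such as box C/D and box H/ACA, with medians of 0.11 and 1.94, and the tRNA class pools all isotypes. Type within a class could thus still stand in for length. Low-abundance transcripts were argued against by 0.715 among 601 entries with a base mean of at least 100. GC content was argued against by a partial rank correlation of 0.416 in 187 box C/D snoRNAs. Each of these correlations had a permutation p = 1e-05 (adjusted p = 1.6e-05 over 11 relations). A length bias common to both immunoprecipitations was argued against by -0.0715 for length and control over input (permutation p = 0.021, adjusted p = 0.026), against 0.617 for VEGF over input. Within lists the correlation of length and D held in box C/D snoRNA (0.444), scaRNA (0.477) and cytosolic tRNA (0.469), and did not pass in box H/ACA snoRNA (0.0805, adjusted p = 0.37) or microRNA (0.0591, adjusted p = 0.62). For tRNAs the length is that of the RefSeq gene and not of the mature RNA. The tRNA value also spans isotypes with different medians, so it does not show that longer tRNA molecules differed more. VEGF-A165 may recover longer RNA more, and a size difference in handling the VEGF libraries alone stays open, since it coincides with the groups.

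SNORD113 and SNORD114, 26 box C/D snoRNAs of the chromosome 14 cluster, were below input in 25 entries in each immunoprecipitation in the authors' deposited table. Short length would put other box C/D snoRNAs of 69 to 77 nt as low, and the cluster's median with VEGF-A165 lay -2.31 from those 56 (permutation p = 1e-05). For GC content, the median lay -2.50 from that of 22 of these entries also within the cluster's GC range (p = 1e-05 by permutation). For abundance, it lay -2.18 from that of 39 also within its abundance range (permutation p = 9e-05). The cluster was chosen after its low values were seen, and the permutations tested those same values. The comparison entries were only kept inside the cluster's ranges. These values therefore do not settle length, GC content or abundance. The control over input was also lower than in the 56, by -1.47 (permutation p = 0.00024), and the difference between the immunoprecipitations was not shown to differ from theirs (-0.86, permutation p = 0.071). Of the 26 entries 16 fell with VEGF-A165 against the control, 1 rose and 9 did not pass, with a median difference of -1.46. The permutations count these related genes as independent. Why they were below input stays open, and no biological explanation was tested.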
